A study of Mus musculus with 47 samples.

How the data were processed

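Gene expression was measured in micropunches of the medial prefrontal cortex of adult C3H/HeN mice, an inbred strain. Per the labels, the adversity group combined an injection of lipopolysaccharide, a bacterial product that triggers inflammation, at embryonic day 17 with separation of the pups from their mothers over postnatal days 2 to 14, and brains were taken at 5.5 months. The 47 arrays came from 45 mice, namely 11 control males, 12 adversity males, 10 control females and 12 adversity females. Control male 8 and adversity male 7 each had 2 arrays, which were averaged and counted as 1 mouse. The labels name 2 batches, and the file headers place each batch on 3 of the 6 slides. Control male 8 had 1 array in each batch, so its batch covariate was averaged too, and it entered both fits of a single batch. Each slide held mice of all 4 groups, and all slides shared 1 scan day. The sample titles also hold a middle number from 1 to 3 whose meaning is not given. It was 1 or 2 in males and 2 or 3 in females. The labels name no litter, so some animals may be siblings, and every p-value covers the spread among these mice only.

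Per the labels, 25 ng of total RNA per sample was amplified and labelled with the dye Cy3. Per the file headers, the spots of a one-colour Agilent array were read with Feature Extraction 10.10.1.1, whose processed signal is an intensity on a linear scale after detrending and background subtraction, not scaled between arrays. The deposited spot flags, such as well above background and saturated, take the value 0 or 1. The submitters' processing notes also name limma, with no role given. A deposited table of log2 values lists 36975 probes of the same arrays. Each of its 47 columns correlated best with the log2 signal of its own array (lowest r = 0.989, slopes 0.829 to 0.878), so the scale and direction are settled. All columns had a median of 7.66 and the same sorted values, as quantile normalization gives. The background step and the probe filter behind that table are not given in the sources used here.

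From the scanner files, the log2 of the processed signal was taken and the array's own 75th percentile was subtracted, so levels below are log2 values relative to that percentile. Control spots and 153 probe values marked as outliers on an array were left out, and spots of 1 probe were averaged. Of the 56605 probes, 32994 were named through an accession held in a RefSeq table of mouse genes (assembly GRCm38.p6), 10224 through a symbol and 520 through an older symbol, and 12867 kept the name in the file. The builds of the array and of that table differ, so no coordinates are given. Each gene was represented by its probe with the highest mean over all mice, and 25174 genes well above background in at least 10 mice were tested.

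The number of mice limits the precision here. The 75th percentile of the processed signal ran from 235.7 to 896.6 across arrays (3.80-fold), the share of probes well above background from 59.6% to 71.7% (33755 to 40593 probes), and 0 probes were saturated on any array. Feature Extraction put every quality metric in range for 46 arrays and marked 1, from control female 24, for evaluation. The number of mice gave a median standard error (SE) of 0.08 log2 units per gene within a sex and 0.11 for the difference between the sexes. The repeat arrays of 1 mouse differed with a standard deviation (SD) of 0.28 log2 units over genes in both cases, while arrays of different mice of the same group differed with a median SD of 0.41 in adversity males and 0.46 in control males.

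Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (version 1.17.8). One fit over all 45 mice with batch as a covariate gave the effect of adversity in males, in females, their mean and their difference (the male minus the female effect), and male minus female among controls. Tests were two-sided, and p-values were adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. The female and male effects rest on separate controls, and their correlation across genes was tested by 100 permutations of treatment within sex and batch. A bound of the form "at least N-fold" was used for a gene that was not well above background in any mouse of a group. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background.

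Before the data were examined, the groups, tests, alternatives, the rule for named genes and 33 gene lists were fixed. The lists cover cell types, cortical layers, the neighbouring striatum, stress hormones, neuronal activity, transmitters, immunity, metabolism, translation and the clock, and 2 of them serve only as a check of sex. The other 31 lists, each with at least 5 measured genes, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted together over the 4 comparisons of adversity (124 tests). Camera with the correlation estimated for each list is given beside it. After the data were seen, a further test was added, in which each mouse's score for a list, the mean over its genes of the level minus the gene's mean, was compared by 100000 permutations of treatment within sex and batch.

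The rule for named genes took up to 12 genes with the largest change in each direction among those past the threshold, passing over clone, Gm, LOC and accession names. A direction with fewer than 10 was filled to 10 with the genes of lowest p, given as values that did not pass. Every list member past the threshold, the 2 to 4 members with the largest moderated t of each list described, and all measured genes of the sex check were also taken. Some genes that the rule takes are not reported here.

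The gene test was tested on simulated data with known changes. It recovered 76 of 100 genes changed by 0.5 log2 units in males and 96 of 100 changed by 1, and called 11 of 24952 unchanged genes. For the difference between the sexes it recovered 62 and 89 of 100 genes and called 10 unchanged genes, and for both sexes together 61 and 89 with 9 unchanged genes. The list test called a list shifted by 0.4 in females for females, the difference and both sexes. It called 0 lists that share no gene with it, and any list that shares one was left out of that count. The simulated genes varied independently, while the real lists had estimated inter-gene correlations of up to 0.73. The simulation thus does not show how often the list test passes on correlated genes.

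The alternatives were normexp background correction (offset 50) of the mean signal and local background, quantile normalization, the deposited log2 table, no filter on dim probes, only genes well above background in all mice, every probe on its own, no batch term, slide as a block, batch with the title number, each batch alone, only the first array of the 2 repeated mice, array weights, eBayes with trend and robust settings, and only the groups of the comparison. Leaving out each mouse in turn, female controls 26 and 36, and male controls 6 and 20 were added after the data were seen. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No mouse was left out of the comparisons.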

Results

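Expression was measured in the medial prefrontal cortex, a region that regulates emotion and stress responses, of 45 adult mice of both sexes raised under early adversity or under control conditions. The groups held 11 control and 12 adversity males and 10 control and 12 adversity females. Sex labels fitted the arrays. Xist, the RNA that silences 1 X chromosome in females, lay between -1.07 and -0.09 in the 22 females and between -8.14 and -5.28 in the 23 males. The Y-linked RNA helicase gene Ddx3y lay between -3.39 and -2.29 in males and between -7.92 and -6.30 in females, with 0 mice overlapping for either gene. The first 4 principal components held 17.0%, 10.7%, 8.22% and 5.49% of the variance. The second component separated females by title number, from -46.1 to -14.8 with number 2 and from -10.2 to 20.3 with number 3. Arrays of control females 26 and 36 lay farthest from their group (root mean square residual 1.73 and 1.60, next highest 1.30), and leaving out both was tried after this was seen.

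The first comparison asked how adversity affected the adult cortex of males. Interferon-stimulated genes, which encode antiviral proteins, were lower in adversity males, with a median log2 change of -0.38 and estimates below 0 for all 23 measured members. The mean score of this list was below the control mean in 12 of 12 adversity males (score difference -0.40, SE 0.11, 12 against 11 mice). Its camera test passed (adjusted p = 2.44e-17), but not with an estimated correlation (adjusted p = 0.102 with an estimated correlation), while the permutation of scores over mice passed (adjusted p = 0.0291). Ddx58, the RNA sensor RIG-I, differed by -0.42 (SE 0.10), Irf7, a transcription factor of the interferon response, by -0.60 (SE 0.17), Ifit1 by -0.75 (SE 0.22) and Usp18, which trims the ubiquitin-like protein ISG15 from its targets, by -0.72 (SE 0.20), each below the control mean in 12 of 12 mice. Over all genes tested 0 of the 23 members passed, and adjusted over the list alone 15 fell.

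The median change of interferon-stimulated genes in males was -0.34 in batch 1 alone, -0.34 in batch 2 alone and -0.38 with slide as a block. Control males 6 and 20 had scores of 0.99 and 0.94 for this list, against 0.47 or less in the other control males, and without both the median change was -0.21. Markers of microglia, the immune cells of the brain, and of endothelial cells, which line vessels, had medians of the same sign. The median change was -0.11 over 18 microglial genes (adjusted p = 0.00188, and adjusted p = 0.348 with an estimated correlation) and -0.09 over 15 endothelial genes (adjusted p = 0.00523, and 0.359 as the adjusted p with an estimated correlation). Without control males 6 and 20 both calls ended, at -0.01 for microglia (adjusted p = 0.300) and -0.05 for endothelial cells (adjusted p = 0.137), as they did with normexp background (adjusted p = 0.414 and 0.184). With array weights the medians were -0.04 for microglia (adjusted p = 0.0307) and -0.03 for endothelial cells, whose call ended (0.352), as it did with no filter on dim probes (0.0773). Microglia also missed the threshold in batch 1 (-0.01, against -0.10 in batch 2 and -0.10 with slide as a block) and endothelial cells in batch 2 (-0.03, against -0.06 and -0.09). Laptm5, a lysosomal protein gene of immune cells, was the microglial member that fell when adjusted over the list alone (-0.28, SE 0.09, lower in 11 of 12 mice).

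Complement and antigen presentation genes were lower in adversity males as well, with a median of -0.33 and all 22 members below 0. The score was below the control mean in 12 of 12 mice, but below the mean of the 9 controls other than mice 6 and 20 in 7 of 12, against 12 of 12 for interferon-stimulated genes. Camera gave an adjusted p of 6.03e-10, with adjusted p = 0.304 with an estimated correlation. None passed over all genes (limma, 0 of 22), and adjusted over the list alone 6 fell, namely H2-K1 (-0.86, SE 0.23), H2-D1, Tap1, Tap2, Psmb9 and C3. H2-K1 and H2-D1 encode MHC class I chains, Tap1 and Tap2 the transporter that loads peptides onto them, and C3 the central complement protein. The median was -0.19 in batch 1, -0.31 in batch 2 and -0.31 with slide as a block, and -0.11 without control males 6 and 20, whose scores were 1.40 and 0.49 (-0.19 without mouse 6 alone), and -0.15 with array weights. Cytokines and inflammatory signalling genes had a median of -0.17 (adjusted p = 0.000296, and adjusted p = 0.348 with an estimated correlation), with Tlr2 at -0.40 (SE 0.15) and Ccl5 at -0.54 (SE 0.24), and -0.04 without these 2 mice and -0.08 with array weights.

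Oligodendrocyte genes, which serve myelin, had a median change of -0.32 in adversity males (16 of 18 members below 0, 11 of 12 mice below the control mean, adjusted p = 2.64e-06). That call was lost with an estimated correlation (adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone 7 members fell, among them Gjb1, a gap junction protein of myelinating cells (-0.33, SE 0.11), Aspa (-0.43, SE 0.15) and Hapln2 (-0.78, SE 0.30), and 0 passed over all genes. The median was -0.56 in batch 1, -0.09 in batch 2 and -0.30 with slide as a block, and -0.15 without control male 20 (adjusted p = 0.000323). Immediate early genes, which neurons switch on within minutes of activity, had a median of -0.24 (adjusted p = 3.55e-06, and adjusted p = 0.348 with an estimated correlation), with -0.45 in batch 1, -0.14 in batch 2 and -0.27 with slide as a block. The call ended with normexp background (-0.22, adjusted p = 0.0757). Adjusted over the list alone 3 of 22 fell, namely the transcription factor genes Npas4 (-0.92, SE 0.20, lower in 10 of 12 mice) and Nr4a3 (-1.50, SE 0.37, lower in 11 of 12) and the growth-arrest gene Btg2 (-0.65, SE 0.20, lower in 11 of 12).

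Markers of excitatory neurons had a median of 0.12 in adversity males and a score above the control mean in 12 of 12 mice (adjusted p = 0.0328, and adjusted p = 0.314 with an estimated correlation). Slc17a7, the vesicular glutamate transporter of cortical neurons, differed by 0.13 (SE 0.07), and the list median was 0.06 in batch 1, 0.10 in batch 2 and 0.11 with slide as a block. This call ended in batch 1 (adjusted p = 0.319), with quantile normalization (0.0707), in the deposited log2 values (0.121), among genes well above background in all mice (0.0588) and without control males 6 and 20 (0.0526). GABA receptor genes had a median of 0.08 and cholesterol synthesis genes one of 0.08 (adjusted p = 0.0179 and 0.00233, or 0.348 and 0.435 as adjusted p with an estimated correlation). Mitochondrial respiratory chain genes had a median of 0.04, and cytosolic ribosomal protein genes had -0.02, a sign that turned to 0.01 with normexp background (adjusted p = 0.00121 and 0.00188, or 0.601 and 0.615 as adjusted p with an estimated correlation). The mitochondrial call ended in batch 2 (0.01, adjusted p = 0.738), where the test pointed down, and its median was 0.08 with normexp. The ribosomal call ended in batch 1, at 0.01 (adjusted p = 0.342), and with no filter on dim probes (0.153). Without control males 6 and 20 the calls for GABA receptor (0.05), cholesterol (0.05) and mitochondrial (0.02) genes ended too. The remaining lists past the camera threshold in males had medians below 0, namely astrocytes (-0.07), mural cells (-0.13), meninges and fibroblasts (-0.25), choroid plexus and ependyma (-0.22), striatal neurons (-0.11) and glucocorticoid-induced genes (-0.08). Their adjusted p-values ran from 0.00131 to 0.0265, and from 0.278 to 0.544 as adjusted p with an estimated correlation. Control male 18 had a striatal score of 1.19, against 0.16 or less in the other control males, and no striatal value without this mouse is given here. The meningeal median was -0.34 in batch 1 and 0.07 in batch 2, and the glucocorticoid call ended without control male 6 (-0.02). Normexp background ended the calls for astrocytes (adjusted p = 0.694), mural cells (0.148), meninges (0.168), striatal neurons (0.127) and glucocorticoid-induced genes (0.596), and leaving out males 6 and 20 ended those for meninges (0.154), choroid plexus (0.0939), glucocorticoid-induced genes (0.154) and cytokines (0.158). The astrocyte median was -0.03 with array weights and -0.04 without males 6 and 20, both still past the threshold. Array weights ended the calls for mural cells (-0.07, adjusted p = 0.205), meninges (-0.00, 0.728) and choroid plexus (-0.17, 0.0766), and the choroid call also ended in the deposited values (-0.04, 0.0825). Batch 1 alone ended those for astrocytes (-0.05, adjusted p = 0.223), striatal neurons (-0.01, 0.470) and glucocorticoid-induced genes (-0.06, 0.378), and batch 2 alone that for choroid plexus (-0.14, 0.307). With no filter on dim probes meninges (0.0790), striatal neurons (0.222) and glucocorticoid-induced genes (0.153) did not pass. Camera sets a list against the other genes, so its direction need not be the sign of the median. Of the 18 lists past the threshold in males its direction was up for 4 and down for 14. It was up for 9 and down for 5 with normexp background, and for 2 and 15 with quantile normalization. With no filter on dim probes it was up for 6 and down for 9, and without control males 6 and 20 for 0 and 8. Over all genes the median change in males was 0.01, but -0.05 with normexp and -0.04 with no filter.

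By single gene, 0 of 25174 passed in males by limma, with 2844 at an unadjusted p under 0.05 (1731 higher and 1113 lower in adversity males). Independent genes without any change would give 1259, and random splits of the mice gave a median of 694 and up to 3369, with 2 of 100 splits as large, the real one included. The number was 8189 with normexp background, 5051 of 37008 genes with no filter on dim probes and 1572 without control males 6 and 20. No splits were run for these settings. Over all genes the median change was -0.05 with normexp and -0.04 with no filter, against 0.01 in the main fit. Part of these larger counts may thus reflect a shift shared by most genes, which was not tested. The smallest adjusted p in the main fit was 0.298. Values that did not pass included Nlrc5, an activator of MHC class I genes (-1.32, SE 0.30), the RNA-binding protein gene Zfp36 (-0.55, SE 0.14) and the interferon-inducible GTPase gene Gvin1 (-0.62, SE 0.17), each below the control mean in 12 of 12 mice. Nlrc5 was well above background in 7 of 11 control and 3 of 12 adversity males. Dep1 (-0.21, SE 0.06) and Sertad3 (-0.22, SE 0.06) were also among the lowest p-values. On the other side stood Acsbg3 (0.45, SE 0.12), Rad51ap1 (0.28, SE 0.07), Spa17 (0.34, SE 0.09), Napg (0.20, SE 0.06), Riox2 (0.18, SE 0.04) and Ino80 (0.18, SE 0.05), with Mblac2, Maea, Lancl1 and Bbs5 between 0.13 and 0.16. Counts of 1 and 2 genes passed with normexp background and with array weights.

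**Figure D1:**
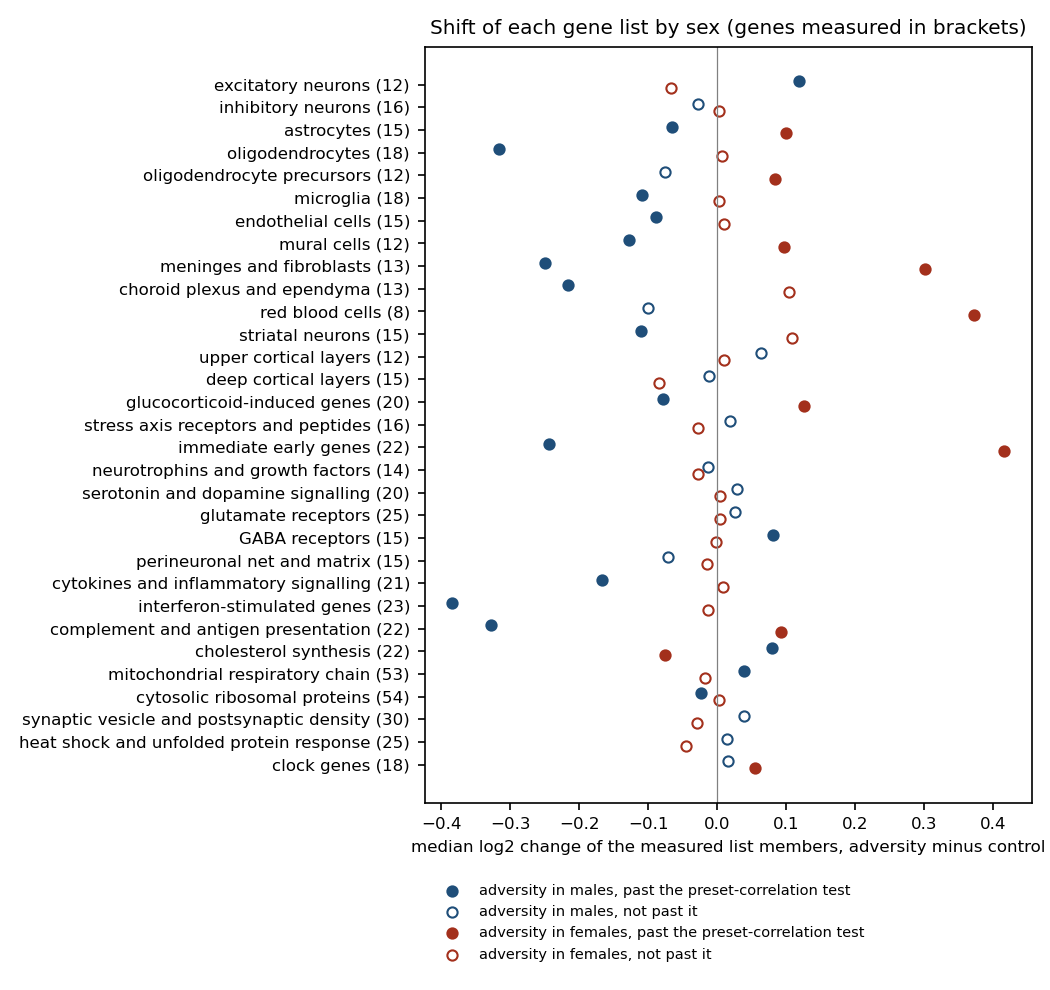
Median log2 change of the measured members of each list, adversity minus control (horizontal axis), in males and in females, with the number of genes measured in brackets. Filled points passed the camera test with a preset correlation, and 0 of them did with an estimated correlation. Interferon-stimulated genes lay at -0.38 in males and -0.01 in females, and immediate early genes at -0.24 and 0.42.

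The second comparison asked the same question in females. Klf2, a transcription factor gene induced by blood flow in vessels and present in resting lymphocytes, rose in adversity females by 0.84 (SE 0.15, 12 of 12 mice above the control mean, limma adjusted p = 0.0329). Its mean log2 level was 0.70 ± 0.38 (SD, n = 12) against -0.14 ± 0.40 (SD, n = 10) in controls. It was the 1 gene past the threshold, with 1243 genes at an unadjusted p under 0.05 (median 1152 over random splits of the mice, 45 of 100 as large). That number was 2238 without control female 36, 2810 with array weights and 564 with normexp background, settings for which no splits were run. The change of Klf2 was 0.93 in batch 1 (adjusted p = 0.402), 0.75 in batch 2 (adjusted p = 0.269) and 0.84 with slide as a block (adjusted p = 0.0250). Its call ended with batch and title number as covariates (0.80, adjusted p = 0.0763), without control females 26 and 36 (0.79, adjusted p = 0.193) and with no filter on dim probes (adjusted p = 0.0551). Leaving out any 1 of 15 females (controls 24, 26, 28, 30, 32, 34, 36 and 42 and adversity mice 25, 29, 35, 37, 39, 43 and 45) ended the call, with an adjusted p up to 0.147 and a change between 0.79 and 0.93.

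Immediate early genes were higher in adversity females, with a median of 0.42 and 19 of 22 members above 0. The list score was above the control mean in 12 of 12 mice (adjusted p = 2.44e-17). That call was lost with an estimated correlation (adjusted p = 0.102 with an estimated correlation), and the score permutation gave an adjusted p of 0.0796. Adjusted over the list alone 13 of 22 rose, while 0 passed over all genes. Examples were Btg2 (0.82, SE 0.20), the phosphatase gene Dusp1 (0.65, SE 0.19), the AP-1 subunit genes Junb (0.44, SE 0.13) and Fos (0.77, SE 0.27), and Egr4 (0.51, SE 0.16), each above the control mean in 11 or 12 of 12 mice. The median was 0.32 in batch 1, 0.46 in batch 2 and 0.40 with slide as a block. Red blood cell genes were also higher, at a median of 0.37 with all 8 members above 0 and 10 of 12 mice above the control mean. Camera passed (adjusted p = 1.41e-06), but not with an estimated correlation (adjusted p = 0.278), and the score permutation gave an adjusted p of 0.223. Hbb-b2 and Hba-a2, globin chains, differed by 0.39 (SE 0.17) and 0.37 (SE 0.17), and the list median was 0.34 in batch 1, 0.42 in batch 2 and 0.36 with slide as a block.

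Glucocorticoid-induced genes, which respond to the stress hormone corticosterone, had a median of 0.13 in adversity females (15 of 20 members above 0, 11 of 12 mice above the control mean, adjusted p = 6.95e-08). With an estimated correlation the adjusted p was 0.102. Adjusted over the list alone Ddit4, an inhibitor of growth signalling (0.30, SE 0.09), and Pdk4, which restrains glucose oxidation (0.25, SE 0.07), rose, and 0 members passed over all genes. The median was 0.20 in batch 1, 0.04 in batch 2 (adjusted p = 0.143) and 0.13 with slide as a block. Astrocyte genes (0.10) and oligodendrocyte precursor genes (0.08) also had medians above 0 (adjusted p = 4.16e-06 and 2.43e-05, and adjusted p = 0.102 with an estimated correlation for each). Gjb6 and Gja1, the connexins of astrocytes, differed by 0.17 (SE 0.08) and 0.22 (SE 0.11), and the precursor genes Lhfpl3 and Vcan by 0.20 (SE 0.08) and 0.20 (SE 0.09).

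The lists past the camera threshold in females that also lay above 0 were mural cells (0.10), meninges and fibroblasts (0.30), complement and antigen presentation (0.09) and clock genes (0.05), with adjusted p-values from 0.000347 to 0.00473 and from 0.348 to 0.504 as adjusted p with an estimated correlation. The clock call ended without control females 26 and 36 (0.02, adjusted p = 0.403), and female 26 had a clock score of -0.65. The meningeal median was -0.09 in batch 1 and 0.61 in batch 2, and the complement median -0.01 and 0.30. The complement median was 0.17 without control female 26, and 0.05 without control female 30 or adversity female 29. Cholesterol synthesis genes had a median of -0.08 with 21 of 22 members below 0 (9 of 12 mice below the control mean, adjusted p = 0.000216, and adjusted p = 0.359 with an estimated correlation). The median was -0.02 in batch 1 (adjusted p = 0.346), -0.15 in batch 2 and -0.08 with slide as a block, and -0.05 without control female 32. Camera pointed up for 9 and down for 1 of the 10 lists past the threshold in females, but for 10 and 4 with normexp background. Interferon-stimulated genes had a median of -0.01 in females (adjusted p = 0.680).

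Among single genes that did not pass in females, the kinase gene Pim3 (0.45, SE 0.10, limma adjusted p = 0.383), Tcim (0.61, SE 0.15), Zfp36 (0.52, SE 0.14), Gadd45g (0.46, SE 0.13), Hs3st3a1 (0.47, SE 0.12), Txnip (0.43, SE 0.11), Fzd2 (0.27, SE 0.07) and Amotl2 (0.20, SE 0.05) had the lowest p-values above 0. Below 0 these were Ntf5, a neurotrophin gene (-0.89, SE 0.24), L3mbtl4 (-0.36, SE 0.10), Cyp20a1 (-0.33, SE 0.08), Sox18 (-0.30, SE 0.09), Klhl25 (-0.25, SE 0.07), Zc3h8 (-0.21, SE 0.06), Slc2a6, Neo1 and Cars.

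The third comparison asked whether adversity acted differently in the sexes. Klf2, Zfp36, Btg2 and Npas4 differed in their response, with estimates below 0 in adversity males and above 0 in adversity females. The male minus female effect was -1.22 for Klf2 (SE 0.21, limma adjusted p = 0.0147), -1.07 for Zfp36 (SE 0.20, adjusted p = 0.0351), -1.47 for Btg2 (SE 0.28, adjusted p = 0.0373) and -1.48 for Npas4 (SE 0.29, adjusted p = 0.0402). Zfp36 encodes a protein that speeds the decay of short-lived mRNAs, Btg2 one that slows cell division, and Npas4 a transcription factor switched on by neuronal activity. Of 12 adversity males, 0, 0, 1 and 2 lay above the control mean for Klf2, Zfp36, Btg2 and Npas4, and of 12 adversity females 12, 11, 12 and 11 did.

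In levels, Npas4 was 1.97 ± 0.63 in adversity males (SD, n = 12) against 2.88 ± 0.38 in control males (n = 11), and 3.59 ± 0.35 in adversity females (n = 12) against 3.03 ± 0.52 in control females (n = 10). Btg2 was -0.06 ± 0.43 against 0.60 ± 0.53 in males and 1.38 ± 0.40 against 0.57 ± 0.53 in females. Klf2 was -0.61 ± 0.22 against -0.22 ± 0.38 in males. Zfp36 was -3.29 ± 0.23 against -2.74 ± 0.49 in males and -2.39 ± 0.25 against -2.91 ± 0.32 in females. Of 25174 genes 3374 had an unadjusted p under 0.05 (median 1025 over random splits of the mice, 3 of 100 as large). That number was 5080 without control female 36, 6319 without control females 26 and 36 and 951 in batch 1 alone. Past the threshold were these 4 genes, all 4 with a lower male effect. The deposited log2 table instead gave 3 genes above and 7 below 0.

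Within a batch the differences kept their size without passing. Klf2 was at -1.30 in batch 1 (adjusted p = 0.340) and -1.21 in batch 2 (0.161), Zfp36 at -1.27 (0.118) and -0.92 (0.182), Btg2 at -1.67 (0.999) and -1.42 (0.161), and Npas4 at -1.60 (0.999) and -1.47 (0.161). With slide as a block they were -1.22, -1.08, -1.49 and -1.49 with adjusted p-values of 0.0105, 0.0319, 0.0108 and 0.0220. Klf2 passed in all 45 fits that left out 1 mouse. Zfp36 passed in 32, Btg2 in 28 and Npas4 in 22, with adjusted p-values up to 0.0809, 0.0809 and 0.0886. The mice whose absence ended a call were 1, 9, 11, 16, 18, 21, 29, 30, 32, 34, 35, 43 and 45 for Zfp36, these and 13, 14, 22 and 25 for Btg2, and in addition 5, 7, 8, 26, 27 and 39 for Npas4. Zfp36 missed the threshold with quantile normalization (adjusted p = 0.0533), and its difference was -0.62 with normexp background and -0.66 in the deposited log2 values. The other Btg2 probe stood at -1.32 and did not pass. With no filter on dim probes only Klf2 passed, with Zfp36, Btg2 and Npas4 at adjusted p = 0.0584, 0.0607 and 0.0652, and with every probe tested these 3 were at 0.0535, 0.0563 and 0.0607.

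**Figure D2:**
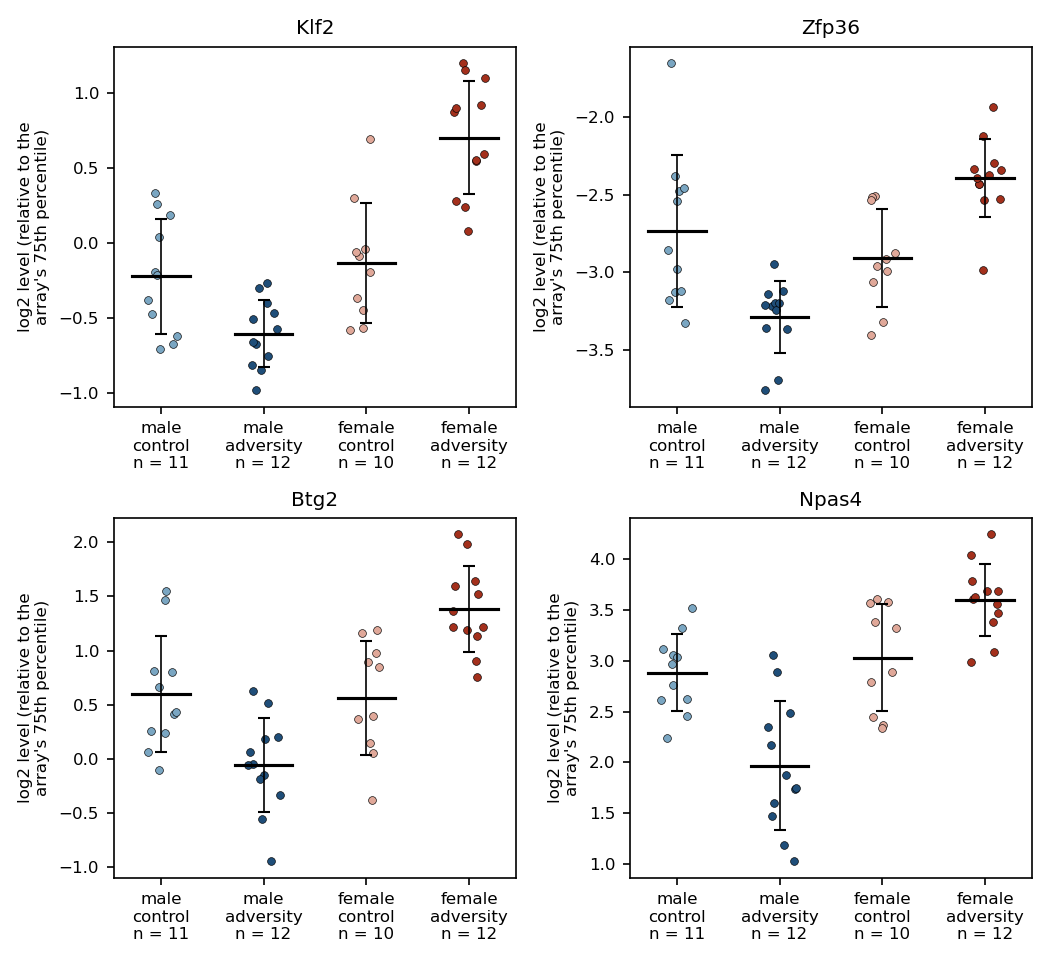
Log2 level relative to the array's 75th percentile (vertical axes) of Klf2, Zfp36, Btg2 and Npas4 in each mouse, with the group mean (bar) and SD (whiskers). For Klf2 all 12 adversity females lay above the mean of the control females and 0 of 12 adversity males above that of the control males.

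Immediate early genes as a list set the sexes apart, with a median male minus female effect of -0.67 and 19 of 22 members below 0. Camera passed (adjusted p = 1.49e-14), though not with an estimated correlation (adjusted p = 0.102 with an estimated correlation). The permutation of scores over mice also passed (score difference -0.70, SE 0.17, adjusted p = 0.0124), with 11 of 12 adversity males below and 12 of 12 adversity females above their control means. Npas4 and Btg2 passed over all genes, and adjusted over the list alone 14 members fell, among them Nr4a3 (-2.29, SE 0.52), Fos (-1.43, SE 0.37), Arc, a synaptic activity gene (-1.22, SE 0.35), Dusp1 (-0.92, SE 0.27) and Junb (-0.72, SE 0.19). The median was -0.76 in batch 1, -0.60 in batch 2 and -0.68 with slide as a block.

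**Figure D3:**
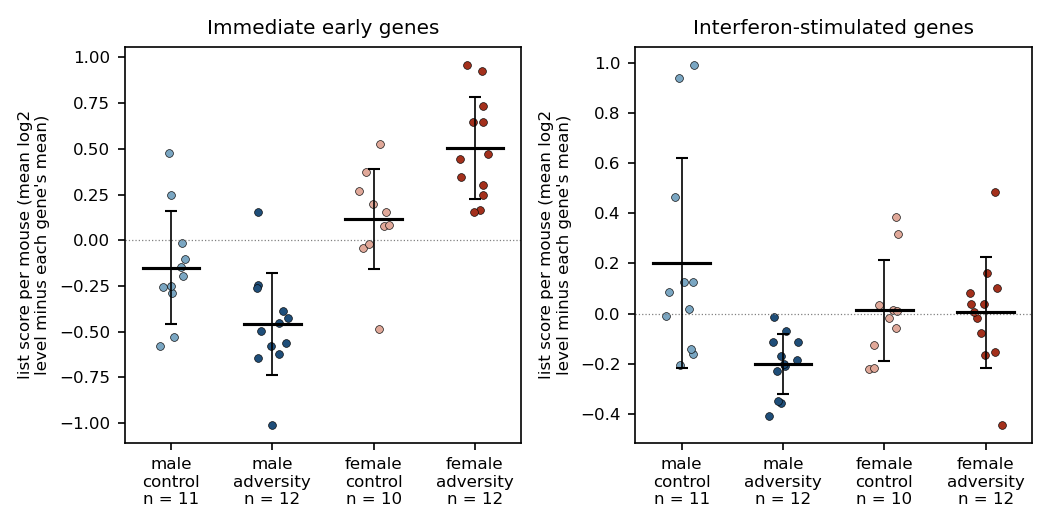
Score per mouse (vertical axes, mean over the list's genes of the log2 level minus the gene's mean) for immediate early genes and interferon-stimulated genes, with the group mean (bar) and SD (whiskers). Immediate early scores averaged -0.46 in adversity males and 0.50 in adversity females, against -0.15 and 0.11 in controls. Interferon scores of the 12 adversity males lay between -0.41 and -0.01, and those of control males reached 0.99.

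The immune lists differed between the sexes in the same direction. Complement and antigen presentation genes had a median of -0.45 (22 of 22 members below 0, adjusted p = 6.31e-10) and interferon-stimulated genes one of -0.43 (22 of 23 below 0, adjusted p = 2.17e-09), each with adjusted p = 0.304 with an estimated correlation. Adjusted over the list alone, H2-D1 (-0.78, SE 0.23), H2-K1 and Psmb9 fell in the first list and Lgals3bp (-0.49, SE 0.16), Ddx58, Rsad2 and Ifih1 in the second, with 0 over all genes. The complement median was -0.21 in batch 1, -0.68 in batch 2 and -0.45 with slide as a block, and the interferon median -0.28, -0.46 and -0.41. Without control males 6 and 20 they were -0.22 and -0.26, and the complement median was -0.29 without mouse 6 alone. Glucocorticoid-induced genes had a median of -0.23 (15 of 20 below 0, adjusted p = 3.48e-06, and adjusted p = 0.179 with an estimated correlation). Of these, 6 fell when adjusted over the list alone, among them the metallothionein gene Mt2 (-0.44, SE 0.13), Nfkbia (-0.40, SE 0.12) and Ddit4 (-0.39, SE 0.13). Their median was -0.25 in batch 1, -0.20 in batch 2 and -0.23 with slide as a block.

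Cholesterol synthesis genes went the other way, with a median of 0.17 and 21 of 22 members above 0 (adjusted p = 5.02e-05, and adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone Fdps (0.27, SE 0.10), Msmo1 (0.26, SE 0.09), Fdft1, Sqle and Nsdhl were among those that rose. The median was 0.11 in batch 1, 0.20 in batch 2 and 0.17 with slide as a block. Astrocyte genes had a median of -0.17 (adjusted p = 3.48e-06, and adjusted p = 0.102 with an estimated correlation), with Gja1 at -0.43 (SE 0.15) and Gjb6 at -0.33 (SE 0.11) among 4 that fell over the list alone. Oligodendrocyte genes had a median of -0.32 (adjusted p = 0.000296, and adjusted p = 0.435 with an estimated correlation), but -0.89 in batch 1 and 0.16 in batch 2, and -0.21 without control male 20. The other 11 lists past the camera threshold were cell or region markers below 0 (from -0.12 in endothelial cells to -0.55 in meninges), cytokines (-0.16), and mitochondrial (0.06) and ribosomal (-0.03, but 0.01 with normexp background) genes. Their adjusted p-values lay between 0.000175 and 0.0328, and between 0.237 and 0.628 as adjusted p with an estimated correlation. Normexp background ended the calls for microglia, endothelial cells, red blood cells and striatal neurons (adjusted p = 0.0532 to 0.724). Leaving out control males 6 and 20 ended those for microglia, endothelial cells, cytokines and mitochondrial genes (adjusted p = 0.0605 to 0.434). Camera pointed up for 2 and down for 16 of the 18 lists. It pointed up for 7 and down for 11 with normexp background, and for 5 and 11 with no filter on dim probes.

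Genes next in order did not pass. Amotl2 (-0.35, SE 0.07) and Cars, a tRNA synthetase gene (0.22, SE 0.05), had a limma adjusted p of 0.0508, and Txnip, which binds thioredoxin, stood at -0.72 (SE 0.15). The others below 0 were Tcim (-0.92, SE 0.21), Tent5a (-0.49, SE 0.11), Fzd4 (-0.38, SE 0.08) and Tob1 (-0.37, SE 0.08). Above 0 stood Acsbg3 (0.77, SE 0.17), L3mbtl4 (0.60, SE 0.14), Doc2a, a calcium sensor of transmitter release (0.34, SE 0.08), Crybg2 (0.33, SE 0.08), Tbc1d24 (0.28, SE 0.07), Camkmt (0.27, SE 0.06), Neo1 (0.25, SE 0.06), Tbcc (0.20, SE 0.05) and Kif1a, an axonal motor gene (0.16, SE 0.04). Without control females 26 and 36 the number of genes past the threshold was 427 (319 above and 108 below 0), with all 4 of the genes above among them.

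The fourth comparison took the mean effect over both sexes. Interferon-stimulated genes had a median of -0.15 with all 23 members below 0 (adjusted p = 3.25e-15, and adjusted p = 0.129 with an estimated correlation), and 12 of 12 males but 6 of 12 females lay below their control mean. Ddx58 differed by -0.20 (SE 0.07), Usp18 by -0.40 (SE 0.14) and Irf7 by -0.33 (SE 0.12), and 0 members passed over all genes or adjusted over the list alone. The median was -0.22 in batch 1, -0.10 in batch 2 and -0.14 with slide as a block. Oligodendrocyte genes had a median of -0.16 (17 of 18 below 0, adjusted p = 0.000101, and adjusted p = 0.416 with an estimated correlation), with -0.07 in batch 1, -0.21 in batch 2 and -0.14 with slide as a block, and -0.08 without control male 20 (adjusted p = 0.00880). The other 8 lists past the camera threshold had medians from -0.09 (complement and antigen presentation, whose call ended without control male 6 at -0.03, and whose median was -0.06 without control female 26) to 0.13 (red blood cells). Their adjusted p-values lay between 0.00200 and 0.0444, and between 0.304 and 0.746 as adjusted p with an estimated correlation. Camera pointed up for 4 and down for 6 of the 10 lists. It pointed up for 12 and down for 4 with normexp background, and for 10 and 4 with no filter on dim probes. Among these 8 lists, leaving out control females 26 and 36 ended the calls for GABA receptors, cytokines, complement, mitochondrial and clock genes. Without control males 6 and 20 camera pointed up for 4 and down for 2. The calls for microglia, endothelial cells, cytokines, complement, GABA receptors and mitochondrial genes ended.

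No gene passed for both sexes together by limma (0 of 25174, 643 at an unadjusted p under 0.05, median 943 over random splits of the mice and 81 of 100 as large, smallest adjusted p 0.997). The values of lowest p included Zpbp2 (0.45, SE 0.15), Hs3st3a1 (0.28, SE 0.08), Pim3 (0.22, SE 0.07), Galns (0.17, SE 0.06), Pdk4 (0.15, SE 0.05), Pex7 (0.12, SE 0.04), Dnajc25, Rpp38, Zfp433 and Gpkow above 0, and Defb14 (-0.52, SE 0.16), Adgrg3 (-0.35, SE 0.12), Spata31 (-0.30, SE 0.10), Scgb3a2 (-0.25, SE 0.07), Tcl1b5 (-0.20), Mccc1os (-0.25), Orai3 (-0.07) and Sertad3 (-0.14, SE 0.04) below 0. Across the 25174 genes, which are not independent replicates, the male and female effects had a Pearson correlation of -0.164, and 27 of 100 permutations of treatment lay as far from 0 (permutation p = 0.277, range -0.305 to 0.40). It was 0.20 in batch 1 and -0.33 in batch 2.

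Lists that passed in none of the 4 comparisons were inhibitory neurons, upper and deep cortical layers, stress axis receptors and peptides, neurotrophins and growth factors, serotonin and dopamine signalling, glutamate receptors, perineuronal net and matrix, synaptic vesicle and postsynaptic density, and heat shock and unfolded protein response. The lowest of their adjusted p-values was 0.0544, for upper cortical layers over both sexes (median 0.03). In males the serotonin and dopamine list had a median of 0.03 and a mean of -0.03, which differ in sign.

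The fifth comparison set control males against control females, as a check of sex and a scale for the other effects. Genes of the Y chromosome were higher in males, with Eif2s3y, a translation factor subunit, at least 49.7-fold, Uty, a histone demethylase, at least 19.96-fold and Ddx3y at least 5.18-fold (limma adjusted p = 5.25e-20, 1.18e-24 and 7.49e-31). Xist was at least 21.9-fold higher in females (adjusted p = 1.05e-29). The multicopy Y gene Sly differed by 2.40 (SE 0.22), and its 3 other probes had the same sign. Of X-linked genes that escape silencing, Kdm5c (-0.31, SE 0.04) and Ddx3x (-0.28, SE 0.05) were lower in males. Eif2s3x differed by 1.84 at 1 probe and -0.66 at the other, so this close relative of Eif2s3y is reported as uncertain. Kdm5d, Sry, Utp14a and Kdm6a, the other measured genes of the check, did not pass.

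Outside the sex chromosomes, control males had higher Etnppl, an astrocyte enzyme gene (0.86, SE 0.17, adjusted p = 0.00175), Pipox (0.78, SE 0.20), Fam107a (0.61, SE 0.12) and Ankrd34c (0.55, SE 0.11). The clock-driven genes Ciart (0.70, SE 0.18), Dbp (0.70, SE 0.20, adjusted p = 0.0498) and Per3 (0.41, SE 0.11) were higher too, and control female 26 stood far below the other control females in all 3. Without control females 26 and 36 these were 0.57, 0.46 and 0.33, all still past the threshold. Control females had higher Dmkn (-1.74, SE 0.29), Ntf5 (-1.43, SE 0.25), Adgrf4 (-1.30, SE 0.30), Otop3 (-1.12, SE 0.23), Fancd2 (-1.02, SE 0.28), Fgf3 (-1.02, SE 0.26) and Ces1f (-1.34, SE 0.30), in each of which female 26 stood far above the others. Without 26 and 36 these lay between -1.44 and -0.63 and all passed. With normexp background the values were smaller and the calls ended for Adgrf4 (-0.64), Fgf3 (-0.52), Fancd2 (-0.43), Otop3 (-0.34) and Ces1f (-0.16), while Dmkn (-1.04) and Ntf5 (-0.53) still passed. In the deposited values Fancd2 (-0.59) and Fgf3 (-0.68) did not pass, and Ntf5 (-0.79) and Otop3 (-0.55) did. Pipox, Ciart and Ankrd34c were at 0.40, 0.40 and 0.26 with normexp. Other probes of Fam107a (0.16), Fgf3 (-0.17), Etnppl (0.51), Ciart (0.44) and Dbp (0.67) did not pass. Spata21 (-0.98, SE 0.12, but -0.42 with normexp and -0.64 in the deposited log2 values) and Tcfl5 (-1.05, SE 0.26) were also higher in females, and Xpnpep2 (-1.48, SE 0.38) lost its call without these 2 mice. With normexp background Tcfl5 (-0.19) and Xpnpep2 (-0.17) did not pass. The title number was 1 only in males and 3 only in females, so it is partly tied to sex. With it as a covariate 208 genes passed, 185 of them shared with the 514, and the calls for Etnppl (adjusted p = 0.121), Pipox (0.215), Adgrf4 (0.112), Fancd2 (0.175), Fgf3 (0.104), Tcfl5 (0.0753) and Xpnpep2 (0.108) ended.

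Among the 22 immediate early genes, 4 passed and were lower in control males, with Egr1 at -0.58 (SE 0.16), Fosb at -0.56 (SE 0.15), Egr3 at -0.52 (SE 0.10) and Ier5 at -0.44 (SE 0.12). No list was tested for this comparison, and Egr1 (adjusted p = 0.153), Fosb (0.130) and Ier5 (0.0758) missed the threshold without control males 6 and 20, as they did with batch and title number (0.118, 0.0985 and 0.154) and with normexp background (0.0883, 0.0514 and 0.0643). Egr1 also missed it with slide as a block (0.0557), and Egr1 and Ier5 with quantile normalization (0.0671 and 0.0599) and in the deposited values (0.0656 and 0.0549). The cell-cycle inhibitor gene Cdkn1a was at -0.74 (SE 0.15). Smaller differences were found for the heat shock and unfolded protein response genes Hspa8 (-0.25), Creld2 (-0.28) and Ddit3 (-0.19). Ddit3 was at 0.04 in batch 1 and -0.02 in the deposited log2 values. The respiratory chain genes Ndufa6 (-0.11) and Ndufa7 (-0.14), and Crtac1 (-0.35, with female 26 far above the others), were also lower in control males. The endothelial genes Flt1 (0.27), Slco1a4 (0.30) and Abcb1a (0.26), the astrocyte gene Slc4a4 (0.24), Mef2c (0.21) and Dlx6os1 (0.30) were higher in control males. Ddit3, Ndufa6 and Ndufa7 missed the threshold with normexp background, quantile normalization and in the deposited values, and Hspa8 with quantile normalization (adjusted p = 0.0736) and in the deposited values (0.0522). Creld2 (0.0648) and Dlx6os1 (0.0541) also missed it with quantile normalization. Without males 6 and 20 the calls for Flt1, Abcb1a, Dlx6os1, Ndufa6, Ndufa7, Pipox, Ciart, Dbp, Per3, Tcfl5 and Fancd2 ended as well (adjusted p = 0.0573 to 0.135). The calls for Slc4a4, Crtac1, Creld2, Mef2c, Flt1, Abcb1a, Dlx6os1, Ndufa6 and Ndufa7 ended with batch and title number (adjusted p = 0.0601 to 0.605). Those for Ankrd34c, Pipox, Dbp, Mef2c, Abcb1a and Creld2 ended with normexp background (0.0524 to 0.149), and those for Dbp, Abcb1a, Dlx6os1, Creld2 and Ndufa6 with slide as a block (0.05001 to 0.0584). Without females 26 and 36 Abcb1a and Mef2c did not pass (0.0659 and 0.0627). In all, 195 genes were higher and 319 lower in males (4163 at an unadjusted p under 0.05). Quantile normalization gave 214 higher and 218 lower, the deposited log2 values gave 198 and 211, and normexp gave 109 and 116. The count was 104 in batch 1, 102 in batch 2 and 562 with slide as a block. It rose to 1018 without control females 26 and 36 and to 973 without 36 alone, and fell to 337, 334 and 300 without control male 20, control female 34 and control male 16.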

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

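The tests with the title number, without control males 6 and 20, of array signal against distance, and the permutation of list scores were chosen after the results were seen, as were the values without control females 26 and 36. Permutation p-values of list scores in this part are unadjusted unless marked as adjusted.

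Among the 80 sets of values of the 10 control females tested for a single animal far from the rest, 19 held one, and 17 of the 19 were control female 26. Chance gives about 1 in 20 for independent sets that were not picked. These sets share the same mice, and many hold genes taken because they passed the threshold, so that rate is no yardstick for the count. In control female 26 Ciart (-3.49), Dbp (2.28, against 4.45 to 5.48 in the other 9) and Per3 (-0.90) lay far below the other control females. Dmkn (1.53), Ntf5 (-0.29), Ces1f (-2.39), Adgrf4 (0.64), Otop3 (-1.96), Fancd2 (-0.44), Fgf3 (0.66) and Crtac1 (3.65) lay far above them. By list score, female 26 was far above the others for serotonin and dopamine signalling (0.35), perineuronal net and matrix (0.72) and cytokines and inflammatory signalling (0.71), and far below for glutamate receptors (-0.28), GABA receptors (-0.24) and clock genes (-0.65). The other 2 were Egr1 in control female 36 (2.52, against 3.32 to 4.11) and the oligodendrocyte precursor score of control female 44 (0.15).

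Effects of adversity that differed between males and females by the test of the difference itself were those of Klf2 (-1.22), Zfp36 (-1.07), Btg2 (-1.47) and Npas4 (-1.48) among single genes. Among lists, the male minus female effect was -0.67 for immediate early genes, -0.55 for meninges and fibroblasts, -0.48 for red blood cells, -0.45 for complement and antigen presentation, -0.43 for interferon-stimulated genes, -0.32 for oligodendrocytes, -0.30 for choroid plexus and ependyma, -0.27 for striatal neurons, -0.23 for mural cells, -0.23 for glucocorticoid-induced genes, -0.17 for astrocytes, -0.16 for cytokines and inflammatory signalling, -0.15 for oligodendrocyte precursors, -0.14 for microglia and -0.12 for endothelial cells. It was 0.17 for cholesterol synthesis, 0.06 for the mitochondrial respiratory chain, and -0.03 for cytosolic ribosomal proteins, which turned to 0.01 with normexp background. With an estimated correlation 0 of these 18 lists passed by camera (lowest adjusted p = 0.102), and the score permutation kept immediate early genes (adjusted p = 0.0124). The striatal value includes control male 18, whose score was 1.19, against 0.16 or less in the other control males.

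Immediate early genes moved apart in the sexes. A difference between the batches as the whole cause was excluded, since the weaker of the shifts of the list score within a batch was -0.71 (SE 0.24, permutation p = 0.00521). With scores of excitatory neurons, oligodendrocytes, striatal neurons, meninges and red blood cells as covariates the shift was -0.85 (SE 0.20, permutation p = 5e-05). These cell types, as scored, were excluded as the whole cause. Others, such as astrocytes and mural cells, were not covariates and stay open. With the title number as a covariate it was -0.73 (permutation p = 9e-05), which excludes a mere level difference between title numbers. Number 1 occurred only in males and 3 only in females, while number 2 occurred in all 4 groups. With number 2, scores ran from -0.62 to 0.15 in 4 adversity males and from -0.53 to -0.02 in 3 control males. They ran from 0.16 to 0.96 in 4 adversity females and from -0.04 to 0.52 in 5 control females. With number 1 they ran from -1.01 to -0.24 in adversity males and from -0.58 to 0.48 in control males. No test within a title number was run, so a response that depends on title number stays open. A response to adversity that depends on sex may underlie the pattern, as a hypothesis from the same data. These genes respond within minutes to handling, and the order and time of dissection are not in the labels, so an effect of the day of collection stays open and untested.

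Interferon-stimulated genes were lower in adversity males. Within each batch the shift of the list score held (weaker value -0.34, unadjusted permutation p = 0.0259), which excludes the batches as the whole cause. Without control males 6 and 20 it was -0.24 (SE 0.08, unadjusted permutation p = 0.00222), so part of the shift remained. These p-values are for 1 list taken from all those tested, and none adjusted over the lists was computed without these mice. With all mice, an unadjusted score p of 0.00148, for excitatory neurons in males, gave an adjusted p of 0.05425. Whether the list would pass without males 6 and 20 is thus not shown, and its call may depend on them. With the scores of microglia, endothelial cells, meninges, oligodendrocytes and red blood cells together as covariates it was -0.15 (SE 0.07, unadjusted permutation p = 0.00560). That is smaller in size than the -0.20 set beforehand for excluding the cell mix, though past the test's threshold. A different mix of these cells and lower interferon signalling thus cannot be told apart, and an effect of adversity in males stays open. Which of these scores took up the shift was not tested. Without males 6 and 20 the medians were -0.01 for microglia (adjusted p = 0.300) and -0.05 for endothelial cells (0.137), but the test with covariates was not run without them.

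The number of genes with a sex difference in the response rose from 4 to 427 without control females 26 and 36. Only 1 of the 45 pairs of control females, this pair itself, gave as many (next highest 175 for 24 and 36), so leaving out any pair does not give such a count. This pair was chosen for lying farthest from its group, so its rank among the pairs is no independent support. On the array of female 26, 0.473% of the genes called without the pair lay over 2 log2 units from their group. A local fault of that size was thus excluded as the whole cause. A smaller local shift could also remove calls and was not tested. That array did hold 31 probes, close together, over 3 log2 units below their group. Low array signal stays open. Distance from the group went with a low 75th percentile (Spearman rho = -0.32, p = 0.0312 over 45 mice, -0.22 without these females), yet the 10 dimmest other arrays lay between 0.865 and 1.21, so low signal and a difference of these animals cannot be told apart, and no biological explanation was tested.

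Treatment was also reassigned at random among the mice of a sex, and sex among the controls for the comparison of sex, 100 splits per comparison with the real one included. By the rule set beforehand, under 5 of 100 splits as large, chance was unlikely for single genes with a sex difference (1 split reached the real 4, highest other 1). Sex among controls (2 splits, real 514, highest other 571) and lists in males (3 splits, real 18, highest other 18) also met that rule. Other splits reached these 2 counts, so chance is not excluded as a source of their size. For genes in males (real 0, highest other 1) and over both sexes (real 0, highest other 0) all 100 splits reach a real count of 0, so the test could not decide. Chance was not excluded for genes in females (5 splits, real 1, highest other 16). Nor was it excluded for lists in females (14, real 10, highest other 14), for the sex difference (5, real 18, highest other 20) and over both sexes (30, real 10, highest other 16). Other splits called a median of 10 lists in males, so the list test with a preset correlation passes often in these mice without adversity. The 16 genes of 1 female split against the real 1 may point to a structure of these samples other than adversity, which was not tested, and chance is not excluded as its source. A structure seen in the females was the title number, which separated them on the second principal component. It was 3 in 8 of 12 adversity females and 5 of 10 control females, and the splits did not keep it. Whether it gave the 16 genes was not tested.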

How the results depend on the processing

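Leaving out each mouse, female controls 26 and 36, or male controls 6 and 20, and the score permutation were chosen after the results were seen. For every change below the cause was not tested, except that each batch alone holds fewer mice. No paired analysis was possible because the repeat numbers mark repeat arrays of 1 animal. The number of mice limits precision.

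Genes in males numbered 0, but 1 with normexp background and 2 with array weights. In females 1 gene passed, but 0 with no filter on dim probes, batch and title number, batch 1, batch 2, without females 26 and 36, or only the groups compared. For the sex difference (4 genes) the count was 10 in the deposited table, 1 with no filter on dim probes, 8 among genes well above background in all mice, 1 with every probe, 10 with slide as a block, 11 with batch and title number, 0 in batch 1 (951 at an unadjusted p under 0.05 by limma), 0 in batch 2 (4621), 83 with array weights, 427 without 26 and 36, and 7 without 6 and 20. For sex among controls (514) it was 225 with normexp, 208 with batch and title number, 104 in batch 1, 102 in batch 2, 1290 with array weights, 1018 without 26 and 36, and 178 with only the groups compared. Of the 56 lists, 0 passed with an estimated correlation in any comparison, and 2 by the score permutation (1 in males, 0 in females, 1 for the sex difference, 0 over both sexes). Lists in males (18) numbered 11 in batch 1 and 8 without 6 and 20. Lists over both sexes (10) numbered 16 with normexp, 6 in batch 1, 6 without 26 and 36, and 6 without 6 and 20. The correlation of effects (-0.164) was -0.444 with normexp, -0.322 in the deposited table, -0.333 among genes well above background in all mice, 0.205 in batch 1 and -0.333 in batch 2.

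Direction reversed for mitochondrial genes in males in batch 2 (by the test, median 0.0079) and over both sexes in batch 2 (-0.0333), ribosomal genes in males with normexp (0.011) and in batch 1 (0.012) and for the sex difference with normexp (0.0129), meninges (-0.0941) and complement genes (-0.0081) in females in batch 1, oligodendrocytes for the sex difference in batch 2 (0.1595), and Ddit3 among controls in batch 1 (0.0411). Over both sexes, cytokines were at 0.0072 with array weights and -0.0081 without 6 and 20 (reversed by the test), and complement genes at 0.0033 and -0.0033. The other list values numbered 705 with the same call and 123 weaker, where the median changed sign but not the test direction for meninges in males in batch 2 (0.0691), endothelial cells for the sex difference with array weights (0.0214), and over both sexes microglia in batch 1 (0.0208) and mitochondrial genes with array weights (-0.0033). Called genes numbered 583 the same and 183 weaker.

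Without 1 mouse, counts ran from 0 to 0 in males, 0 to 1 in females, 1 to 29 for the sex difference, 0 to 0 over both sexes and 300 to 973 for sex among controls, where 300 came without control male 16, 334 without control female 34, 337 without control male 20 and 973 without control female 36. The female count was 0 without any 1 of 24, 25, 26, 28, 29, 30, 32, 34, 35, 36, 37, 39, 42, 43 and 45. For the sex difference it was 29 without 36, 11 without 15, 8 without 2, 7 without 46, 2 without 13, 14, 22 or 25, and 1 without 1, 9, 11, 16, 18, 21, 29, 30, 32, 34, 35, 43 or 45. Lists ran from 52 to 60, 16 to 20 in males, 10 to 13 in females, 16 to 21 for the sex difference and 6 to 12 over both sexes (6 without control male 6), and the correlation from -0.236 to -0.0889.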

Other observations

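The comparisons of single list members in this part were read after their values were seen.

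Some members of lists that did not pass as a whole passed when adjusted over the list alone. Hsd11b1, whose enzyme regenerates active glucocorticoid, fell in adversity females (-0.25, SE 0.07, adjusted p over the list alone 0.0213, 11 of 12 mice below the control mean). Grm8, a presynaptic glutamate receptor, had a male minus female effect of 0.44 (SE 0.11, adjusted p over the list alone 0.0107), with 12 of 12 adversity males and 2 of 12 adversity females above their control mean. Dlx6os1, a non-coding RNA of inhibitory neurons, had one of -0.36 (SE 0.11, adjusted p over the list alone 0.0458), with 3 of 12 males and 12 of 12 females above it.

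Control male 6 had high scores for complement and antigen presentation (1.40), cytokines (1.40), interferon-stimulated genes (0.99), glucocorticoid-induced genes (0.72) and microglia (0.49), and a low score for red blood cells (-0.93). Control male 20 had high scores for oligodendrocytes (1.29), choroid plexus and ependyma (1.19) and interferon-stimulated genes (0.94). Control male 18 had a high score for striatal neurons (1.19).

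The Y-linked gene Eif2s3y was well above background in adversity females 29 (-2.96) and 27 (-3.43), and Uty in adversity female 29 (-4.18), while Ddx3y was so in 0 of 12.

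On the array of control female 26, 31 probes lay over 3 log2 units below their group, against 3 or fewer on other arrays. Their median distance to the nearest of them was 1.41 spots, against 22.4 spots for random sets of probes (p = 0.000999, the smallest that 1000 sets can give).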
